A study of Mus musculus with 12 samples.

How the data were processed

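Total RNA from 12 liver samples was hybridised to Affymetrix Mouse Gene 1.1 ST arrays, one array per sample. The samples came from female BALB/cByJ mice aged 2.5 months that carried Pml (wt) or lacked it (KO). They formed 6 groups of 2 arrays: untreated mice of each genotype, and mice of each genotype killed 2 h or 6 h after an intraperitoneal injection of 300 mg/kg acetaminophen (APAP) in warmed PBS. A vehicle injection of the untreated mice is not given in the sources used here. Groups were taken from the sample titles, and for 1 wt array at 2 h, whose title is shortened, from its source name. That each sample came from a separate animal is not given in the sources used here, so p-values measure the spread between these samples.

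Per the labels, the authors processed the arrays in Affymetrix Expression Console with RMA, with no version given. The deposited values are normalized intensities on a linear scale, with an array median of 79.9 to 90.1, and log2 was taken here without a pseudocount. Between 133 and 286 probe sets per array lay below 1, of which 1 to 15 carried at least 1 gene symbol. The table held 35556 probe sets. Of these, 21218 carried 1 gene symbol and stood for 18820 genes, 1881 carried several symbols and 12457 carried none. Symbols came from the annotation of the platform's probe sets. The RefSeq gene table of assembly GCF_000001635.26 (GRCm38.p6) was used to check symbols and to find which genes neighbour each other. Probe sets with several symbols or none were left out of the gene tests. No array was left out.

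Tested genes had a probe set with exactly 1 symbol and a mean log2 value of at least 5 over the 12 arrays. For the 1386 genes with more than 1 probe set, the one with the highest mean was used. This left 17052 genes. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) as a model of 6 group means over all 12 arrays, with 6 residual and 4.33 prior degrees of freedom. Each p-value is two-sided and was adjusted over all tested genes within a comparison by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Errors printed after ± with a log2 difference are standard errors of the fit. The 11 comparisons were each treated group against the untreated group of its genotype, KO against wt within each of the 3 conditions and as the mean of the 3, the KO response minus the wt response at each time (the interaction), and 6 h against 2 h as the mean of both genotypes.

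The tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined, except where stated. Pml is named first, in every array. For each comparison the rule then names the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the compared groups, and up to 4 members with the smallest p of each list described. Predicted genes, microRNAs and small nucleolar RNAs were counted and not named. The 29 gene lists were NRF2 targets, p53 targets, immediate early genes, integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, acute phase and metallothioneins, inflammatory cytokines and NF-kB targets, interferon response, hypoxia and glycolysis, perivenous hepatocyte genes, periportal hepatocyte genes, acetaminophen disposition, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR-alpha targets, bile acid synthesis and transport, circadian clock, cell cycle, ribosome biogenesis, and markers of Kupffer cells and macrophages, neutrophils, lymphocytes and NK cells, sinusoidal endothelium, stellate cells and fibroblasts, bile duct, erythroid cells, fat tissue and pancreas. Some genes belong to more than 1 list, and some listed genes had no probe set of their own, among them Gsta1, Gsta2, Bax, Gdf15, Ddit3, Hspa1a, Hspa1b and Ly6g.

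Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists within a comparison, and again with a correlation estimated from the arrays. Of the 319 list results, 122 passed at the preset correlation. With an estimated correlation, 0 passed in limma's camera, 35 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0967. Counts of list members are therefore given for most lists, over all tested genes or adjusted over the list alone.

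Alternatives tried were no filter on the mean, a mean log2 of at least 7, quantile normalization, the mean of a gene's probe sets, a variance trend, a fit of the compared groups only, the replicate number as a block, each array left out in turn, and an estimated correlation in the list tests. After the data were examined, log2 of the value plus 16 was added, and so were counts of list members without each array in turn, first of all without untreated KO replicate 2, for its Pml value, and KO 6 h replicate 2, for its principal component. The fit was tested on 17052 simulated genes. It called 91.0% of log2 changes of 1 for wt at 6 h, 83.6% for KO against wt at 6 h, 100% for the mean of the 3 conditions and 43.3% for the interaction at 6 h. Unchanged genes made up 4.11%, 1.46%, 7.54% and 3.06% of the calls. Rates in real arrays may differ. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. Array number, 2 per group, limits the precision.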

Results

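Gene expression was measured in the liver of mice with Pml (wt) and without it (KO), untreated or 2 h or 6 h after 300 mg/kg acetaminophen (APAP). PML is the scaffold protein of PML nuclear bodies. APAP is oxidised in hepatocytes around the central vein, largely by CYP2E1, to a reactive metabolite that consumes glutathione. Each of the 6 groups held 2 arrays, and every log2 difference is between means of 2 arrays unless stated. The array median of the normalized intensity was 79.9 to 90.1, and the number of arrays limits the precision. Log2 values of probe sets with a mean log2 of at least 5 correlated at 0.9785 to 0.99 between arrays of a group. They correlated at 0.924 to 0.9871 between arrays of different groups. These are correlations across probe sets, which are not independent replicates.

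Pml stood lower in KO than in wt liver in each of the 3 conditions. Its log2 intensity was 8.18 and 8.46 in untreated wt liver, 7.82 and 7.92 at 2 h, and 7.87 and 7.88 at 6 h. In KO liver it was 7.10 and 7.97 untreated, 7.11 and 7.50 at 2 h, and 7.09 and 7.16 at 6 h. The value of 7.97, from the array labelled untreated KO replicate 2, lay within the range of the wt arrays. The platform holds 1 probe set for Pml, and the deleted part of the gene is not given in the sources used here. The mean difference over the 3 conditions was -0.70 ± 0.14 (adjusted p = 0.035). Its call ended after quantile normalization (adjusted p = 0.0624). It also ended without any 1 of 9 arrays (adjusted p of 0.0533 to 0.0991), the exceptions being both untreated KO arrays and KO 2 h replicate 2. Within conditions the difference did not pass, at -0.79 ± 0.24 untreated (adjusted p = 1), -0.56 ± 0.24 at 2 h (adjusted p = 0.184) and -0.75 ± 0.24 at 6 h (adjusted p = 0.0715). After APAP, Pml differed from untreated liver by -0.45 ± 0.24 at 2 h and -0.44 ± 0.24 at 6 h in wt (adjusted p = 0.248 and 0.166). In KO liver the differences were -0.23 ± 0.24 and -0.41 ± 0.24 (adjusted p = 0.493 and 0.211). The KO response minus the wt response of Pml was 0.23 ± 0.33 at 2 h and 0.04 ± 0.33 at 6 h (adjusted p = 0.781 and 0.966), and 6 h differed from 2 h by -0.09 ± 0.17 (adjusted p = 0.708).

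**Figure D1:**
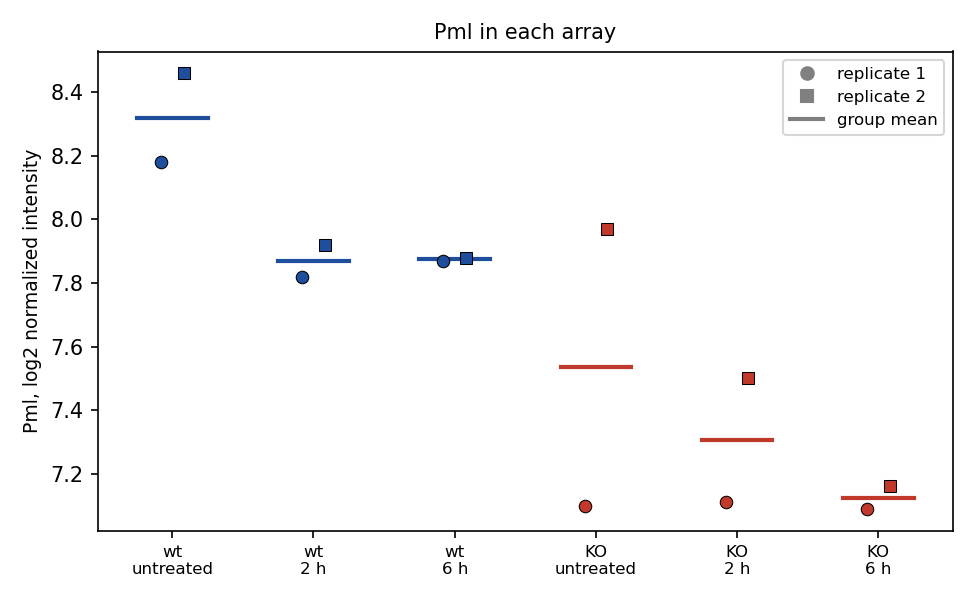
Log2 normalized intensity of Pml (y axis) in the 12 liver arrays by genotype and condition (x axis), with circles for replicate 1, squares for replicate 2 and lines for the mean of each group. The array labelled untreated KO replicate 2 lies at 7.97, within the range of the wt arrays (7.82 to 8.46).

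The first principal component carried 49.4% of the variance of the tested genes and ordered the arrays by time after APAP. Untreated arrays of both genotypes lay at -36.9 to -44.9. At 2 h the wt arrays lay at -2.1 and -2 and the KO arrays at 9.9 and 10.4. At 6 h the wt arrays lay at 44.8 and 42.9 and the KO arrays at 39.7 and 19.8. KO 6 h replicate 2, at 19.8, stood apart from the other 6 h arrays. The second component carried 23.5% and lay at -24.7 to -33.8 in the 2 h arrays of both genotypes. At 6 h it was -2.7 and 12.4 in wt and 28.3 and 35.5 in KO.

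**Figure D2:**
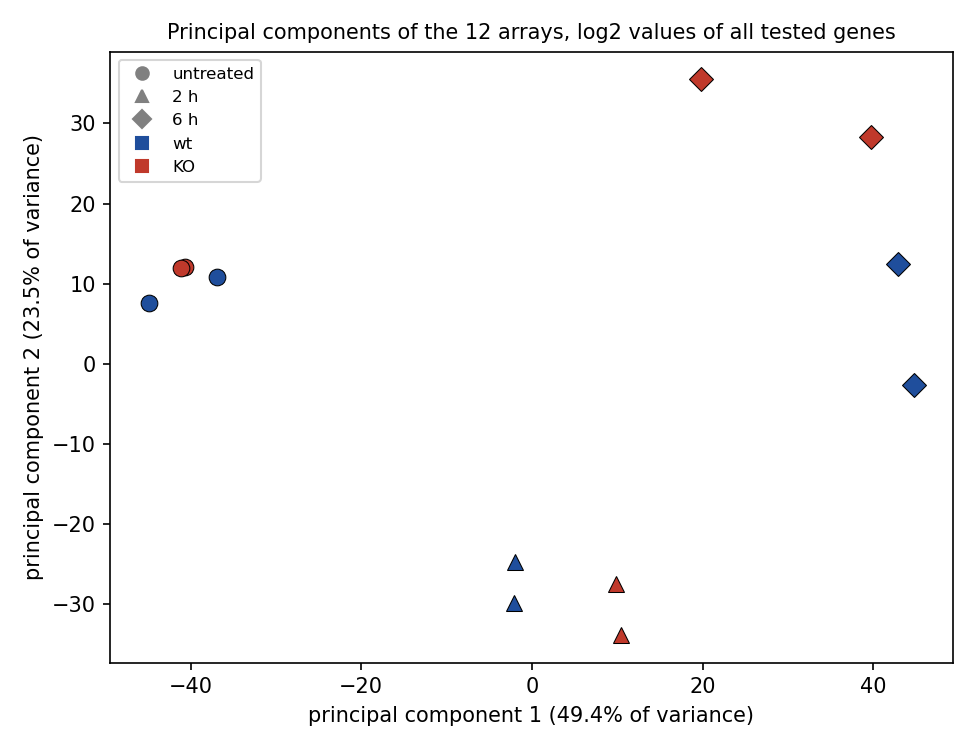
Principal components 1 (x axis, 49.4% of variance) and 2 (y axis, 23.5%) of the log2 values of the tested genes, 1 point per array, coloured by genotype and condition. Untreated arrays lie together on the left, the 2 h arrays at the bottom and the 6 h arrays on the right, where KO 6 h replicate 2 has the lowest first component, 19.8.

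In wt liver, 2 h against untreated asks what APAP changes early when Pml is present. Immediate early genes, the regulators that a stimulus induces first, rose together, 24 of 31 measured members past the test (25 adjusted over the list alone). Fos rose by 5.47 ± 0.32 on the log2 scale and 7 of the 31 did not pass. Atf3, a transcription factor induced by stress, rose by 5.73 ± 0.39 (adjusted p = 4.66e-05, higher in both treated arrays than in both untreated ones). Among p53 targets 8 of 35 rose and 1 fell (9 and 3 adjusted over the list alone), and the risers included the antiproliferative gene Btg2 (4.79 ± 0.39) and Cdkn1a, the cell cycle inhibitor p21 (4.47 ± 0.65). Myom1, which encodes a sarcomere protein, rose by 6.39 ± 0.40 (3.53 with log2 of the value plus 16), Cidec, a lipid droplet protein, by 6.20 ± 0.28, and Maff, a small MAF transcription factor, by 4.68 ± 0.63.

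Lipid metabolism moved in both directions in wt liver at 2 h. Of the genes of fatty acid oxidation and PPAR-alpha targets, 21 of 25 rose (22 adjusted over the list alone), among them the thioesterase gene Acot1 (3.30 ± 0.21) and Plin2, a lipid droplet coat protein (1.22 ± 0.10). Of the fatty acid synthesis genes, 10 of 19 fell (12 adjusted over the list alone, with 1 higher). They included Srebf1, the regulator of lipogenesis (-2.18 ± 0.17), and Acly (-2.22 ± 0.21). Of the cholesterol synthesis genes, 16 of 20 fell and 1 rose (17 and 1 adjusted over the list alone), among them Fdps (-2.49 ± 0.33) and Sc5d (-1.51 ± 0.12). The largest falls by the naming rule included Atp6v0d2, a subunit of the vacuolar proton pump (-3.98 ± 0.53), Thrsp, a lipogenic protein (-3.15 ± 0.51), Mid1ip1 (-2.81 ± 0.30) and Cyp2r1, a vitamin D hydroxylase (-2.58 ± 0.22).

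Metal and acute phase genes split in wt liver at 2 h, with 8 of 26 higher and 3 lower (8 and 4 adjusted over the list alone). Mt1, a metallothionein, rose by 3.65 ± 0.11 and Lcn2 by 2.73 ± 0.22. The list's median was -0.061 and its mean 0.57, so the median and the test, which pointed up, differ in sign (adjusted p = 0.255, and adjusted p = 0.64 with an estimated correlation). NRF2 targets, the genes of the oxidative stress response, rose in 5 of 36 members and fell in 6 (5 and 11 adjusted over the list alone), at a median of -0.096 (adjusted p = 0.261, and adjusted p = 0.64 with an estimated correlation). Those that rose were 3 and those that fell 2 without untreated wt replicate 1 or wt 2 h replicate 2, and 1 fell without untreated wt replicate 2 or wt 2 h replicate 1. The risers included Srxn1 (2.43 ± 0.21) and Hmox1, heme oxygenase 1 (1.65 ± 0.24). Heat shock proteins rose in 5 of 17 (8 adjusted over the list alone), among them Dnajb1 (2.71 ± 0.44), with a median of 0.467, and the count was 1 without untreated wt replicate 2 and 2 without either wt 2 h array. Genes of the integrated stress response rose in 8 of 23 and fell in 1, among them Fgf21 (3.52 ± 0.56), with a median of 0.362, and 5 rose without untreated wt replicate 2 and 4 without either wt 2 h array. Cyp2e1 differed by 0.02 ± 0.09 (adjusted p = 0.902).

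Limma called 2166 genes in wt liver at 2 h, 1114 higher and 1052 lower, and 326 and 201 of these changed at least 2-fold. With 1 array left out the count was 1163 without untreated wt replicate 1, 813 without untreated wt replicate 2, 800 without wt 2 h replicate 1 and 915 without wt 2 h replicate 2. The count of cholesterol synthesis genes called lower fell from 16 to 8, 10 and 9 without untreated wt replicate 2 and wt 2 h replicates 1 and 2. The list tests at the preset correlation gave adjusted p of 1.26e-21 for immediate early genes, 7.54e-19 for fatty acid oxidation, 9.82e-13 for cholesterol synthesis, 1.52e-07 for fatty acid synthesis and 0.0197 for p53 targets. These were adjusted p = 0.262, 0.262, 0.267, 0.262 and 0.393 with an estimated correlation. For heat shock proteins and the integrated stress response they were 0.000435 and 0.000148, and adjusted p = 0.541 and 0.393 with an estimated correlation.

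In wt liver at 6 h, heat shock proteins rose in 16 of 17 measured members, among them Hspb1 (5.21 ± 0.36) and Hsp90aa1 (2.02 ± 0.14). Hspb1 has 2 further probe sets, of which a dim one, with a mean log2 of 5.39, stood at -0.60 and a bright one at 5.28. Genes of the integrated stress response rose in 16 of 23 members and fell in 1 (17 and 1 adjusted over the list alone), among them the amino acid synthesis genes Psat1 (5.43 ± 0.22) and Asns (3.97 ± 0.34). Immediate early genes rose in 26 of 31, with Fos at 5.43 ± 0.32. Ribosome biogenesis genes rose in 21 of 23 (22 adjusted over the list alone), among them the nucleolar genes Ncl (0.99 ± 0.11) and Ddx21 (1.70 ± 0.17). The largest rises included Cxcl2, a chemokine that attracts neutrophils (7.82 ± 1.63) and Sprr1a, known from the cornified envelope of skin (7.33 ± 0.46).

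Inflammatory cytokines and NF-kB targets rose in 18 of 28 members and fell in 1 in wt liver at 6 h, among them Il1b (2.62 ± 0.28), Cxcl1 (3.21 ± 0.32) and the adhesion molecule Sele (1.42 ± 0.14). Neutrophil markers rose in 9 of 14 and fell in 1 (9 and 2 adjusted over the list alone), with S100a8 at 2.67 ± 0.24 and the chemokine receptor Cxcr2 at 3.61 ± 0.34. Kupffer cell and macrophage markers fell in 7 of 16 and rose in 1 (8 and 1 adjusted over the list alone), at a median of -0.33, and 4 fell without either untreated wt array or wt 6 h replicate 1. Among them Timd4, a marker of resident Kupffer cells, fell by 1.26, and Cd68 rose by 1.24 ± 0.14. Bile duct markers rose in 4 of 7, with Sox9 at 1.74 ± 0.39.

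NRF2 targets rose in 12 of 36 members and fell in 8 in wt liver at 6 h, among them Srxn1 (4.42 ± 0.21), Txnrd1, thioredoxin reductase (2.31 ± 0.13), and Hmox1 (3.80 ± 0.24). Of the p53 targets 14 of 35 rose and 6 fell (16 and 8 adjusted over the list alone), with Mdm2, the ubiquitin ligase that degrades p53, at 2.33 ± 0.23 and Tnfrsf10b, a death receptor, at 1.29 ± 0.11. Hypoxia and glycolysis genes rose in 9 of 20 and fell in 1 (9 and 2 adjusted over the list alone), with Adm at 4.35 ± 0.28 and Slc2a1, a glucose transporter, at 2.66 ± 0.28.

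Perivenous hepatocyte genes fell in 16 of 22 in wt liver at 6 h (18 adjusted over the list alone), among them Rgn (-1.74 ± 0.13) and Cyp1a2 (-1.16 ± 0.16). Cyp2e1 differed by -0.11 ± 0.09 (adjusted p = 0.371). Fatty acid synthesis genes fell in 16 of 19, with Scd1 at -1.69 ± 0.11, and cholesterol synthesis genes in 14 of 20 (17 adjusted over the list alone), with Stard4 at -2.27 ± 0.16. Bile acid synthesis and transport genes fell in 14 of 19 (16 adjusted over the list alone, with 1 higher), among them Abcb11, the bile salt export pump (-1.55 ± 0.12). Fatty acid oxidation genes rose in 11 of 25 and fell in 1 (12 and 1 adjusted over the list alone). Genes of acetaminophen disposition stood at a median of -0.107 (adjusted p = 0.848, and adjusted p = 0.852 with an estimated correlation). Keg1 (-4.35 ± 0.53) was among the largest falls.

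Limma called 6554 genes in wt liver at 6 h, 2807 higher and 3747 lower, and 834 and 725 of these changed at least 2-fold. Without untreated wt replicate 2 the count was 4162, and the count of bile acid genes called lower was 9. The count of NRF2 targets called lower was 5 without untreated wt replicate 2 or wt 6 h replicate 1. The list tests gave adjusted p of 5.87e-10 for heat shock proteins, 1.38e-07 for the integrated stress response, 8.31e-17 for immediate early genes, 5.6e-13 for ribosome biogenesis and 3.08e-07 for inflammatory genes. These were adjusted p = 0.269, 0.216, 0.213, 0.248 and 0.213 with an estimated correlation. For neutrophil, bile duct, NRF2, p53 and hypoxia lists they were 0.000136, 0.00427, 0.0287, 0.0269 and 0.000638, and adjusted p = 0.336, 0.213, 0.336, 0.307 and 0.0967 with an estimated correlation. The call of the NRF2 list ended without untreated wt replicate 1 (adjusted p = 0.0688). For perivenous, fatty acid synthesis, cholesterol synthesis, bile acid and fatty acid oxidation lists they were 2.11e-06, 1.53e-07, 2.91e-07, 4.04e-05 and 0.000822, and adjusted p = 0.248, 0.0967, 0.307, 0.0967 and 0.543 with an estimated correlation. Kupffer cell markers did not pass (adjusted p = 0.0812, and adjusted p = 0.623 with an estimated correlation).

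In KO liver, 2 h against untreated asks what differs early after APAP when Pml is lacking. Immediate early genes rose in 28 of 31 members, with Fos at 7.54 ± 0.32, Egr1 at 6.00 ± 0.44 and Egr2 at 5.13 ± 0.25. Heat shock proteins rose in 13 of 17 (15 adjusted over the list alone), among them Hspb1 (4.46 ± 0.36, and -0.03 on its dim probe set) and Hsph1 (2.61 ± 0.31). Fatty acid oxidation genes rose in 23 of 25 (24 adjusted over the list alone), with Acot1 at 3.29 ± 0.21 and the peroxisomal enzyme Ehhadh at 1.24 ± 0.12. Cell cycle genes fell in 10 of 22, among them the replication licensing genes Mcm6 (-1.49 ± 0.18) and Mcm4 (-1.05 ± 0.14).

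NRF2 targets in KO liver at 2 h rose in 9 of 36 members and fell in 10 (9 and 11 adjusted over the list alone). Hmox1 rose by 3.82 ± 0.24 and Osgin1 by 1.64 ± 0.20. The count that fell was 5 without untreated KO replicate 1 and 6 without KO 2 h replicate 1. Interferon response genes fell in 9 of 29 and rose in 1 (10 and 1 adjusted over the list alone), at a median of -0.369, and 4 fell without untreated KO replicate 1. Among them was Psmb8, an immunoproteasome subunit, at -1.08 ± 0.13. Cyp2r1 (-3.64 ± 0.22) and Hsd3b2 (-2.55 ± 0.14) were among the largest falls.

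Limma called 5353 genes in KO liver at 2 h, 1813 higher and 3540 lower, and 357 and 484 of these changed at least 2-fold. After quantile normalization 2544 genes were called higher and 2797 lower, which moved the share higher from 33.9% to 47.6%. The count was 3372 without untreated KO replicate 1 and 2935 without untreated KO replicate 2. The list tests gave adjusted p of 9.12e-24 for immediate early genes, 1.58e-10 for heat shock proteins, 1.18e-16 for fatty acid oxidation and 0.0157 for the cell cycle, each with adjusted p = 0.444 with an estimated correlation. For the interferon list it was 0.0397, and adjusted p = 0.655 with an estimated correlation. This call ended after quantile normalization (adjusted p = 0.0564) and without untreated KO replicate 1 or KO 2 h replicate 2 (0.232 and 0.311). NRF2 targets did not pass (adjusted p = 0.231, and adjusted p = 0.655 with an estimated correlation).

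In KO liver at 6 h, NRF2 targets rose in 19 of 36 members and fell in 4 (20 and 4 adjusted over the list alone). Among them were Srxn1 (4.38 ± 0.21), Txnrd1 (2.19 ± 0.13) and Abcc4, an efflux pump of hepatocytes (2.12 ± 0.17). Heat shock proteins rose in 16 of 17, with Hspb1 at 5.66 ± 0.36 (-0.44 on its dim probe set). Genes of the integrated stress response rose in 13 of 23 and fell in 2 (15 and 2 adjusted over the list alone), with Psat1 at 5.24 ± 0.22. Ribosome biogenesis genes rose in 22 of 23, with Nop56 at 2.40 ± 0.23. Immediate early genes rose in 16 of 31 and fell in 1, among them Atf3 (6.37 ± 0.39) and the phosphatase gene Dusp8 (3.81 ± 0.58). The p53 targets rose in 11 of 35 and fell in 7 (11 and 9 adjusted over the list alone), with Fas, a death receptor, at -1.41 ± 0.18.

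In KO liver at 6 h cholesterol synthesis genes fell in 19 of 20, among them Insig1 (-2.63 ± 0.24) and Stard4 (-2.66 ± 0.16). Perivenous genes fell in 13 of 22 (15 adjusted over the list alone), with Rgn at -1.81 ± 0.13. Periportal hepatocyte genes fell in 7 of 15 (7 lower and 1 higher adjusted over the list alone), among them the gluconeogenic genes Pck1 (-1.64 ± 0.11) and G6pc (-1.45 ± 0.19). Inflammatory genes rose in 6 of 28 and fell in 3, at a median of 0.243. The median was 0.082 without KO 6 h replicate 1 and 0.443 without KO 6 h replicate 2, the array that stood apart. Neutrophil markers were called in 0 of 14 and stood at a median of 0.193 (adjusted p = 0.476, and adjusted p = 0.797 with an estimated correlation), with S100a8 and Cxcr2 not past the test. Hamp2, a hepcidin gene (-4.54 ± 0.26), Depp1 (-4.32 ± 0.59) and Thrsp (-4.64 ± 0.51) were among the largest falls.

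Limma called 5949 genes in KO liver at 6 h, 2700 higher and 3249 lower, and 610 and 637 of these changed at least 2-fold. The count was 3849 without untreated KO replicate 2 and 3845 without KO 6 h replicate 1. Without untreated KO replicate 2 the count of NRF2 targets called higher was 12, that of NRF2 targets called lower 2 and that of p53 targets called lower 3. Without KO 6 h replicate 1 the NRF2 targets called lower were 2 and the p53 targets 7 higher and 4 lower, and without untreated KO replicate 1 the periportal genes called lower were 4. The list tests gave adjusted p of 2.43e-05 for NRF2 targets, 4.82e-10 for heat shock proteins, 3.8e-05 for the integrated stress response, 1.33e-14 for ribosome biogenesis and 1.05e-05 for immediate early genes. These were adjusted p = 0.244, 0.35, 0.35, 0.325 and 0.456 with an estimated correlation. For cholesterol synthesis, perivenous, periportal and inflammatory lists they were 7.73e-10, 3.13e-05, 0.0289 and 0.0289, and adjusted p = 0.343, 0.35, 0.444 and 0.513 with an estimated correlation. The periportal call ended without KO 6 h replicate 1 (adjusted p = 0.0679), and the inflammatory call without KO 6 h replicate 1 or untreated KO replicate 2 (adjusted p = 0.327 and 0.0552). The p53 list did not pass (adjusted p = 0.393, and adjusted p = 0.712 with an estimated correlation).

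The responses of the genotypes overlapped. At 2 h, 678 genes were called higher in both genotypes, against 118.4 if the calls were independent, and 924 were called lower in both, against 218.4. At 6 h these numbers were 1757 against 444.5 and 2324 against 713.9. The log2 differences of wt and KO liver correlated across genes at r = 0.777 and rho = 0.665 at 2 h and at r = 0.798 and rho = 0.712 at 6 h, where genes are not independent replicates. At 6 h, 32 genes were called in opposite directions, and at 2 h 7.

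**Figure D3:**
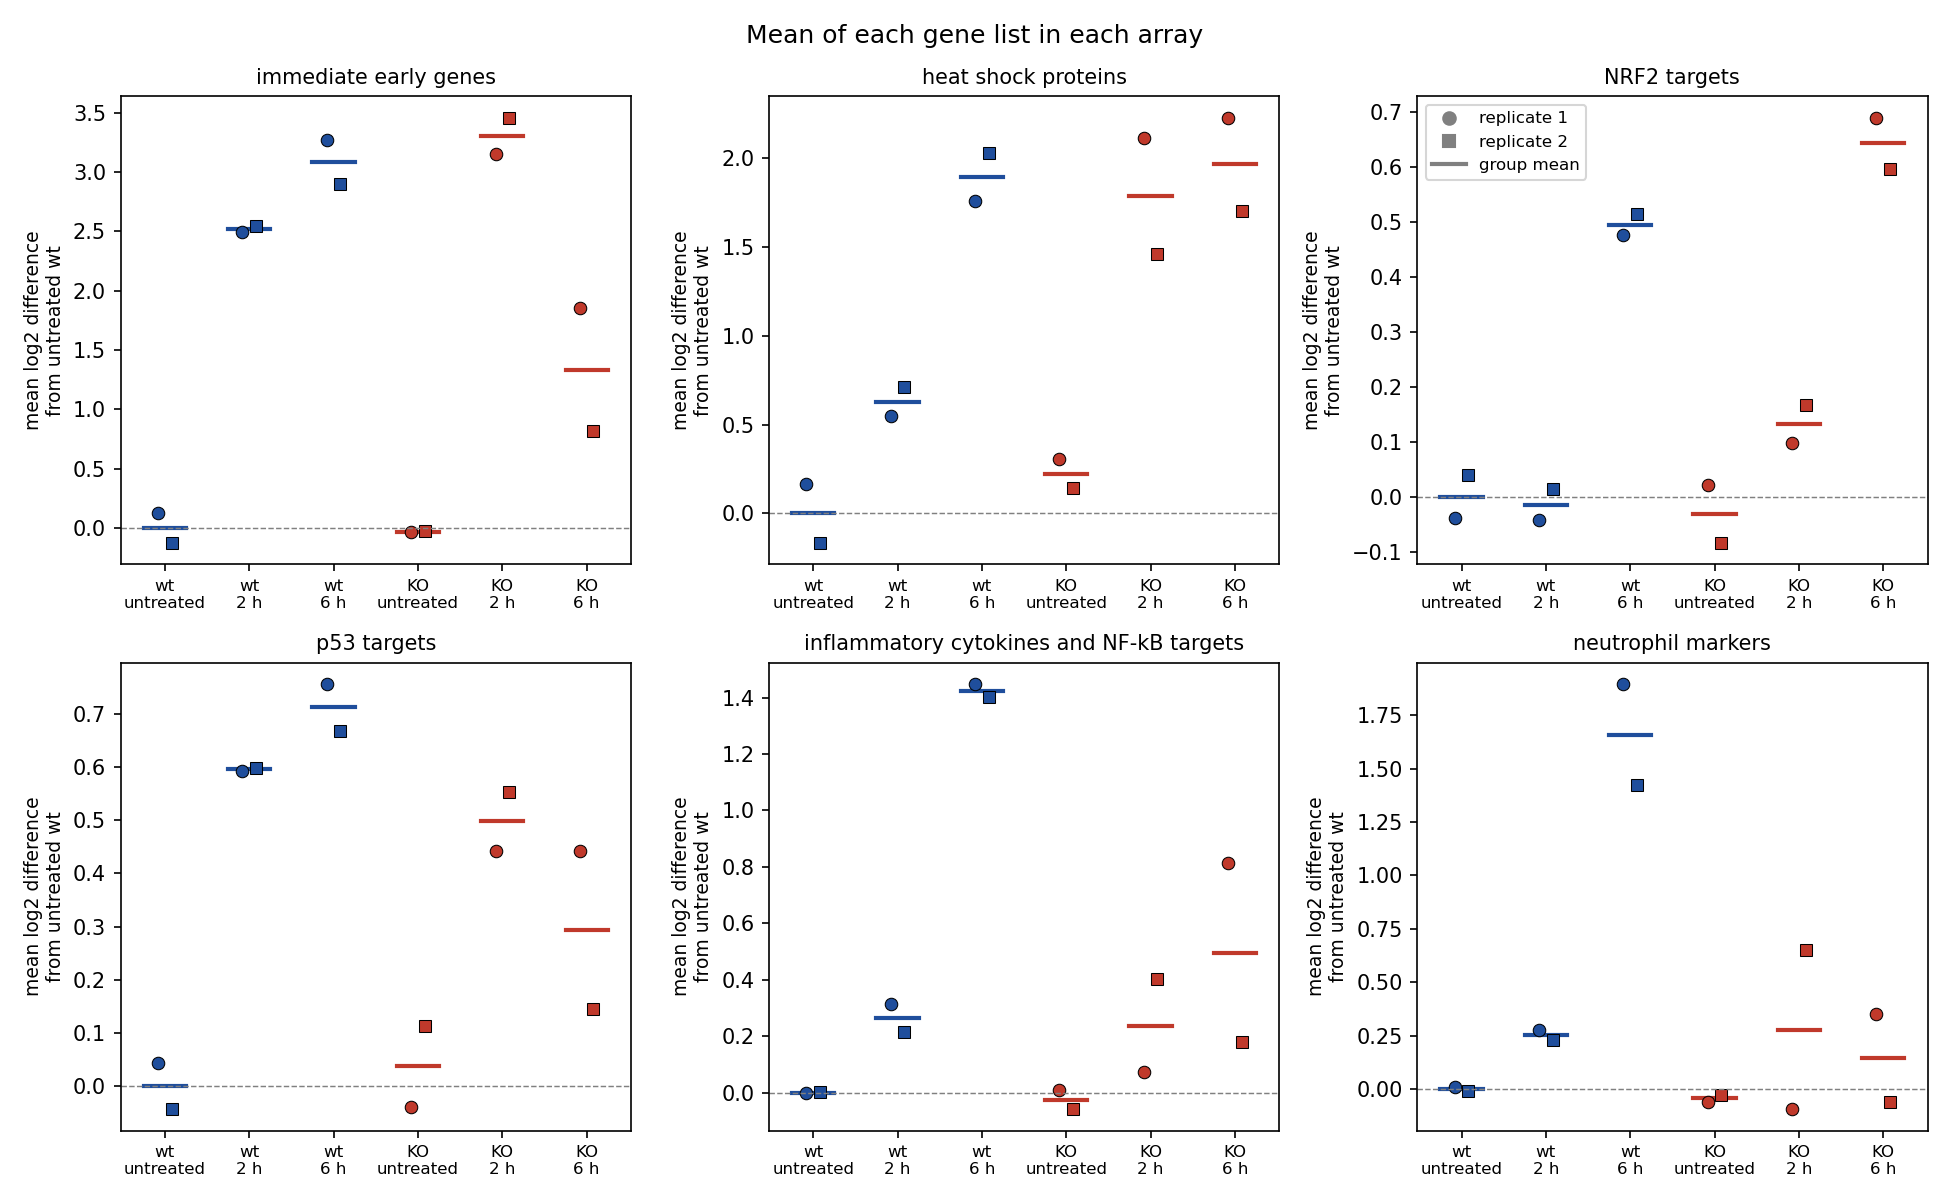
Mean log2 difference from untreated wt liver (y axis) over the measured members of 6 gene lists, 1 point per array, by genotype and condition (x axis). Immediate early genes and neutrophil markers stand lower in the KO than in the wt arrays at 6 h, and heat shock proteins higher in the KO than in the wt arrays at 2 h.

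KO against wt in untreated liver asks what the lack of Pml changes without APAP. Gadd45g, a growth arrest and DNA damage gene, was the only gene called, at 3.21 ± 0.34 (adjusted p = 0.037). Its log2 value was 8.59 and 9.63 in the KO arrays against a wt mean of 5.91. Its call ended after quantile normalization (adjusted p = 0.0522), with no filter (0.0513), with log2 of the value plus 16 (0.0527), in a fit of the compared groups only (0.262) and without any 1 of 7 arrays. These were both arrays of each wt group and untreated KO replicate 2, and the adjusted p was highest without untreated wt replicate 2, at 0.39. Of all tested genes, 660 had an unadjusted p under 0.05, and limma called 0 to 3 genes with 1 array left out. It called 0 without untreated wt replicate 2, untreated KO replicate 2, or any wt array at 2 h or 6 h, and 3 without untreated KO replicate 1 or either KO 6 h array.

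As groups, interferon response genes stood higher in untreated KO than in untreated wt liver, with a median of 0.262 (adjusted p = 1.98e-11, and adjusted p = 0.439 with an estimated correlation). Ifit1, an interferon-induced antiviral gene, differed by 1.10 ± 0.33 (adjusted p = 1). Acute phase genes and metallothioneins stood at a median of 0.169 (adjusted p = 9.2e-06, and adjusted p = 0.29 with an estimated correlation), with Lcn2 at 1.59 ± 0.22 (adjusted p = 0.181). Cell cycle genes stood at a median of 0.138 (adjusted p = 7.66e-07, and adjusted p = 0.29 with an estimated correlation). Fatty acid oxidation genes stood at -0.202 (adjusted p = 1.84e-05, and adjusted p = 0.802 with an estimated correlation). The interferon median was 0.166 and 0.168 without untreated wt replicate 1 and untreated KO replicate 1, and the acute phase median 0.073 without the latter. Without untreated wt replicate 2 the cell cycle and fatty acid oxidation medians were 0.247 and -0.061. Over all genes 0 members of these 4 lists were called. Adjusted over the list alone, 0 interferon genes, 3 acute phase genes and 3 cell cycle genes were higher and 1 fatty acid oxidation gene, Plin2 (-0.48 ± 0.10), lower. NRF2 targets stood at a median of -0.024 and p53 targets at 0.02 (adjusted p = 0.489 and 0.472, and adjusted p = 0.81 and 0.808 with an estimated correlation).

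At 2 h after APAP, heat shock and immediate early genes stood higher in KO than in wt liver. Heat shock proteins were called higher in 7 of 17 members (14 adjusted over the list alone), among them Hspb1 (3.16 ± 0.36, and 0.04 on its dim probe set), Hsph1 (2.16 ± 0.31) and Hsp90aa1 (0.96 ± 0.14). Immediate early genes were called higher in 4 of 31 (8 adjusted over the list alone), among them Egr2 (2.47 ± 0.25), Myc (2.40 ± 0.44) and Fos (1.76 ± 0.32). Cholesterol synthesis genes were called higher in 5 of 20 (13 adjusted over the list alone), among them Msmo1 (1.65 ± 0.24) and Idi1 (1.77 ± 0.29). Of the NRF2 targets 3 of 36 were called higher (6 higher and 1 lower adjusted over the list alone), namely Hmox1 (2.13 ± 0.24), Osgin1 (1.27 ± 0.20) and Txnrd1 (0.81 ± 0.13). Each call named here ended without wt 2 h replicate 1, with adjusted p from 0.0507 for Egr2 to 0.135 for Fos, and all but that of Egr2 without wt 2 h replicate 2, up to 0.195 for Myc. All but those of Egr2 and Hspb1 ended without KO 2 h replicate 1, up to 0.13 for Myc and Idi1. Those of Myc and Fos ended without KO 2 h replicate 2 (adjusted p = 0.0504 and 0.0506), and that of Fos without either untreated KO array (0.051).

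Genes lower in KO than in wt liver at 2 h included Cetn4, a centrin gene, at -3.56 ± 0.17 (adjusted p = 1.17e-05). Its other probe set differed by -0.60 (adjusted p = 0.0486), and the mean of its probe sets by -2.08. Sftpa1, a surfactant protein gene, stood at -2.29 ± 0.20, Col12a1, a collagen gene, at -1.75 ± 0.13, and Gp5, a platelet glycoprotein, at -1.98 ± 0.20. Cd3e, a T cell receptor subunit, stood at -1.83 ± 0.19. Among p53 targets Fas was called lower, at -0.93 ± 0.18 (adjusted p = 0.0359, and 0.071 after quantile normalization). Socs3, an inhibitor of cytokine signalling, was higher by 2.05 ± 0.21 (0.53 on its other probe set), and Irf1, an interferon regulatory factor, by 0.91 ± 0.15 (-0.07 on its other probe set). The calls of Gp5, Cd3e and Socs3 ended without wt 2 h replicate 1 (adjusted p = 0.0507 each). Those of Irf1 and Fas ended without wt 2 h replicate 1 (0.114 and 0.107), wt 2 h replicate 2 (0.194 and 0.24) or KO 2 h replicate 1 (0.0896 and 0.173), and that of Fas without either untreated KO array (0.0522). With the mean of its probe sets Irf1 did not pass (0.0984).

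Limma called 342 genes between KO and wt at 2 h, 70 higher and 272 lower, and 36 and 42 of these differed at least 2-fold. The median difference over all genes was -0.099. After quantile normalization 135 were higher and 102 lower, which moved the share higher from 20.5% to 57%, and a fit of the compared groups only called 52. In that fit 14 of the 36 named calls ended, those of Irf1 (0.0501), Hspb1 and Hsp90aa1 (0.0502), Txnrd1 (0.061) and Fas (0.0878) among them. The count was 8 and 9 without wt 2 h replicates 1 and 2, 19 without KO 2 h replicate 1, 777 without KO 2 h replicate 2, 161 without either untreated wt array and 131 without either untreated KO array. Of the 36 genes, Cetn4, Col12a1 and Sftpa1 kept their call whichever array was left out. Of the others, 33 lost it without wt 2 h replicate 1, 28 without wt 2 h replicate 2, 27 without KO 2 h replicate 1, 3 without KO 2 h replicate 2, 9 without either untreated KO array and 6 without either untreated wt array. Heat shock proteins called higher were 0 without either wt 2 h array, 1 without KO 2 h replicate 1, 13 without KO 2 h replicate 2, 4 without either untreated wt array and 3 without either untreated KO array. In all, 4026 genes had an unadjusted p under 0.05 with all arrays. Immediate early genes called higher were 0 and 1 without wt 2 h replicates 1 and 2, 2 without either untreated KO or either KO 2 h array, and 9 without either KO 6 h array. Cholesterol synthesis genes called higher were 0 without either wt 2 h array or KO 2 h replicate 1, 11 without KO 2 h replicate 2 and 3 without either untreated wt array.

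The list tests between KO and wt at 2 h gave adjusted p of 6.15e-20 for heat shock proteins, 1.38e-13 for immediate early genes, 7.25e-16 for cholesterol synthesis and 0.000173 for NRF2 targets. These were adjusted p = 0.248, 0.358, 0.248 and 0.248 with an estimated correlation. The p53 list did not pass, at a median of -0.154 (adjusted p = 0.874, and adjusted p = 0.902 with an estimated correlation).

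At 6 h after APAP, immediate early, inflammatory and neutrophil genes stood lower in KO than in wt liver. Immediate early genes were called lower in 20 of 31 members (26 adjusted over the list alone), among them Fos (-4.26 ± 0.32), Egr1 (-3.29 ± 0.44) and Ier2 (-2.39 ± 0.22). Inflammatory genes were called lower in 10 of 28 (13 adjusted over the list alone), among them Cxcl1 (-2.41 ± 0.32), Sele (-1.07 ± 0.14) and Tnfaip3, an NF-kB feedback inhibitor (-2.51 ± 0.35). Neutrophil markers were called lower in 8 of 14 (9 adjusted over the list alone), among them S100a8 (-2.40 ± 0.24), S100a9 (-2.61 ± 0.26) and Cxcr2 (-2.98 ± 0.34). Of the p53 targets 8 of 35 were called lower and 1 higher (9 and 2 adjusted over the list alone), among them Plk2 (-1.51 ± 0.22) and Btg2 (-2.67 ± 0.39). Bile duct markers were called lower in 4 of 7, with Cd24a at -1.42 ± 0.28. Lymphocyte and NK cell markers, the other leukocytes of the liver, stood at a median of -0.206 and Kupffer cell markers at 0.221.

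Endoplasmic reticulum chaperones were called higher in 10 of 19 members and lower in 1 in KO liver at 6 h (13 and 1 adjusted over the list alone). Derl3 stood at 1.80 ± 0.18 and Hsp90b1, also known as GRP94, at 0.66 ± 0.14, while Herpud1 was lower at -1.18 ± 0.11. Of the NRF2 targets 6 of 36 were called higher and 1 lower (11 and 3 adjusted over the list alone), with Abcc4 at 1.79 ± 0.17 and Akr1b8 at -0.92 ± 0.14. Cell cycle genes were called higher in 4 of 22 (4 higher and 1 lower adjusted over the list alone), with cyclin D1, Ccnd1, at 2.10 ± 0.29 and Mcm2 at 0.98 ± 0.16. Periportal genes were called lower in 4 of 15 (5 adjusted over the list alone), with Pck1 at -1.35 ± 0.11 and Tat at -0.74 ± 0.10. Fatty acid oxidation genes stood at a median of -0.299, with 6 of 25 lower adjusted over the list alone, and at -0.173 and -0.131 without wt 6 h replicate 1 and KO 6 h replicate 2. Other large differences were Igfbp1, a binding protein of insulin-like growth factors (-3.30 ± 0.24), Gprc5a (-4.02 ± 0.34), Cetn4 (-3.62 ± 0.17, but -0.48 with adjusted p = 0.0519 on its other probe set and -2.05 with the mean of probe sets) and Slc1a4, an amino acid transporter (2.19 ± 0.23). Nnmt, nicotinamide N-methyltransferase, stood at 2.10 ± 0.43.

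Limma called 1538 genes between KO and wt at 6 h, 698 higher and 840 lower, and 56 and 251 of these differed at least 2-fold. The count was 172 without wt 6 h replicate 1, 221 without KO 6 h replicate 2 and 142, 33 higher and 109 lower, in a fit of the compared groups only. With a mean log2 of at least 7 the balance turned, to 825 higher and 563 lower. Of the 79 named and called genes, 26 kept their call whichever array was left out, among them Fos, Egr1, Ier2, Cxcl1, Sele, Tnfaip3, S100a8, S100a9, Cxcr2, Derl3, Herpud1, Abcc4, Ccnd1, Pck1, Tat, Igfbp1, Gprc5a, Cetn4 (on the probe set used) and Slc1a4. Most losses came without wt 6 h replicate 1, 52 genes, and without KO 6 h replicate 2, 43 genes, and each other array ended 14 or fewer calls. Plk2, Btg2 and Akr1b8 lost theirs without wt 6 h replicate 1 (adjusted p = 0.0577, 0.0581 and 0.0622), and Cd24a, Hsp90b1, Mcm2 and Nnmt without it or KO 6 h replicate 2. In the fit of the compared groups only, 52 of the 79 calls ended, those of Cxcl1 (adjusted p = 0.0536), Sele (0.0536), Egr1 (0.0598), Ccnd1 (0.0517) and Tat (0.0611) among them.

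List counts between KO and wt at 6 h moved with the same arrays. Without wt 6 h replicate 1 and KO 6 h replicate 2 respectively, the counts were 6 and 9 for immediate early genes, 6 and 6 for inflammatory genes, 5 and 5 for neutrophil markers, 0 and 3 for p53 targets (5 without wt 6 h replicate 2), 0 and 0 for bile duct markers, 1 and 1 for chaperones, 1 and 1 for NRF2 targets and 1 and 1 for cell cycle genes (2 without wt 6 h replicate 2). In all, 4815 genes had an unadjusted p under 0.05 with all arrays. Periportal genes called lower were 2 without wt 6 h replicate 1. Chaperones called higher were 5 without either untreated wt array and 4 without either untreated KO array, either wt 2 h array or KO 6 h replicate 1. Bile duct markers called lower were 2 without either untreated wt array or KO 6 h replicate 1 and 1 without either wt 2 h array.

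The list tests between KO and wt at 6 h gave adjusted p of 5.9e-18 for immediate early genes, 6.87e-07 for inflammatory genes, 4.12e-08 for neutrophil markers, 0.0017 for bile duct markers and 0.0106 for p53 targets. These were adjusted p = 0.417, 0.417, 0.417, 0.417 and 0.436 with an estimated correlation. For chaperones, fatty acid oxidation, NRF2 and periportal lists they were 2.29e-05, 2.29e-05, 0.0233 and 0.031, each with adjusted p = 0.476 with an estimated correlation. The NRF2 call ended after quantile normalization (adjusted p = 0.102) and without KO 6 h replicate 1 (adjusted p = 0.156), and the periportal call without wt 6 h replicate 2 or KO 6 h replicate 1 (adjusted p = 0.0599 and 0.287). Lymphocyte, Kupffer and cell cycle lists did not pass (adjusted p = 0.128, 0.0589 and 0.85, and adjusted p = 0.591, 0.591 and 0.952 with an estimated correlation).

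**Figure D4:**
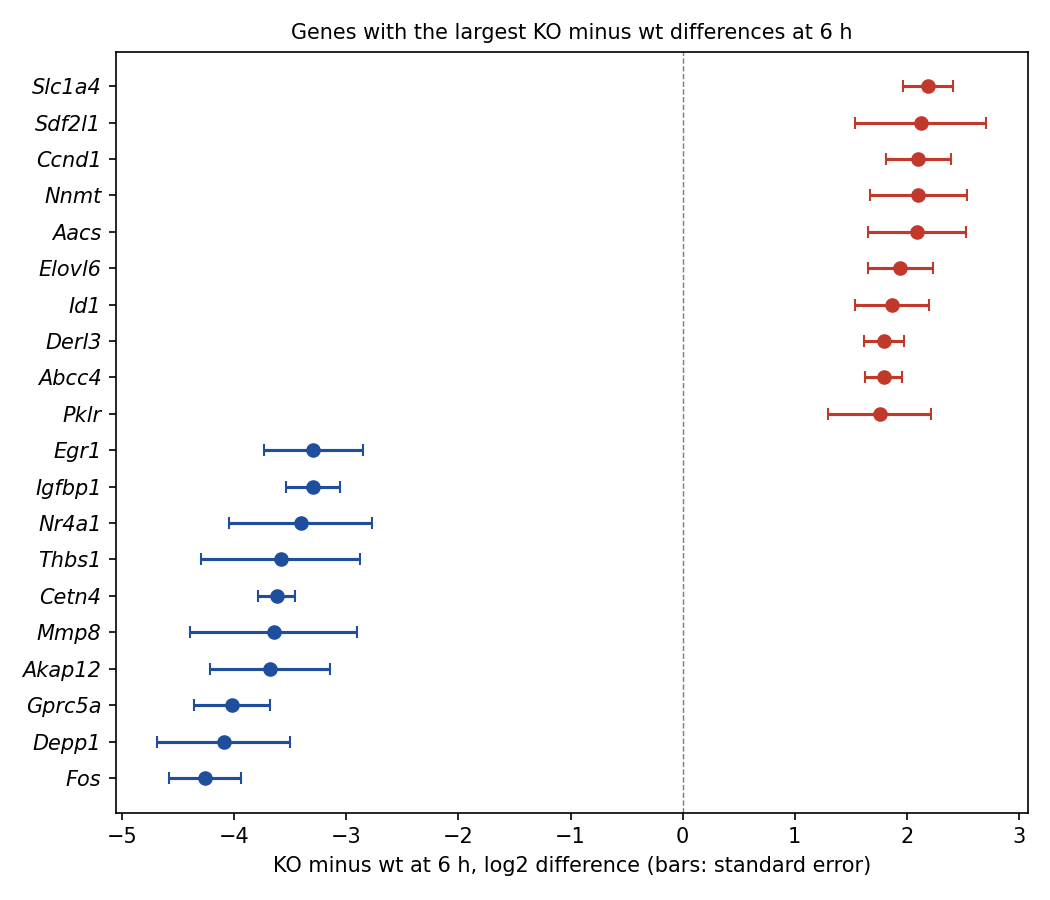
Log2 difference of KO minus wt liver at 6 h after APAP (x axis), with bars for the standard error, for the genes with the 10 largest rises and the 10 largest falls among called genes (y axis). The values run from -4.26 for Fos to 2.19 for Slc1a4.

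As the mean of the 3 conditions, each condition weighted equally, KO stood lower than wt liver in Cetn4 (-2.49 ± 0.10, adjusted p = 1.65e-06). Its other probe set differed by -0.40 (adjusted p = 0.0329), and the mean of its probe sets by -1.44. On the probe set used, Cetn4 had a log2 mean of 4.74 in untreated wt, 8.97 in wt at 2 h and 8.08 in wt at 6 h, and of 4.45, 5.41 and 4.45 in KO. Nnmt was higher by 1.84 ± 0.25, and its KO means of 10.48, 9.92 and 10.05 compared with wt means of 8.96, 8.03 and 7.95. Il18, a cytokine gene (0.86 ± 0.13), Hspb1 (1.59 ± 0.21, and -0.02 on its dim probe set) and Irgm1, an interferon-induced GTPase (0.60 ± 0.07), were higher. Igfbp1 (-1.31 ± 0.14), Pck1 (-0.47 ± 0.06), Herpud1 (-0.48 ± 0.07) and Alas2, the first enzyme of heme synthesis in red cells (-1.24 ± 0.18), were lower on average. In untreated liver these 4 genes stood at -0.16, 0.13, 0.02 and 0.02 against -3.30, -1.35, -1.18 and -2.66 at 6 h. Nnmt and Il18 lie within 20 Mb of Pml on chromosome 9.

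Over the 3 conditions KO stood higher than wt liver at the median in heat shock proteins (0.432, adjusted p = 5.21e-13), interferon response genes (0.279, 1.23e-12), endoplasmic reticulum chaperones (0.259, 6.87e-09), cholesterol synthesis (0.239, 6.33e-09) and NRF2 targets (0.073, 6.08e-05), each with adjusted p = 0.364 with an estimated correlation. Acute phase and ribosome biogenesis lists also passed upward (1.36e-05 and 0.000198, and adjusted p = 0.364 and 0.465 with an estimated correlation). KO stood lower in neutrophil markers (-0.576, 4.22e-06), inflammatory genes (-0.228, 0.00572), immediate early genes (-0.227, 0.00747), bile duct markers (-0.219, 0.0475), fatty acid oxidation (-0.215, 6.55e-07) and sinusoidal endothelial markers (-0.174, 0.0123), with adjusted p = 0.364, 0.403, 0.494, 0.364, 0.379 and 0.409 with an estimated correlation. The p53 targets stood at -0.174 (adjusted p = 0.0566, and adjusted p = 0.391 with an estimated correlation). Immediate early genes stood higher in KO than wt at 2 h and lower at 6 h. Without KO 6 h replicate 2 the immediate early (-0.105) and inflammatory (-0.096) calls ended and fatty acid oxidation stood at -0.132. The immediate early call also ended without KO 2 h replicate 1 or wt 6 h replicate 1. Its median was -0.369 without untreated wt replicate 2 and -0.495 without KO 6 h replicate 1. The endothelial call ended without wt or KO 6 h replicate 1. The bile duct call ended with the replicate block (0.0545) and without several single arrays. Cholesterol synthesis stood at 0.156 without untreated KO replicate 2, and neutrophil markers at -0.378 without KO 2 h replicate 1. Over all genes limma called 4 of 17 heat shock proteins (10 adjusted over the list alone) and, with all arrays, 3 or fewer members of each other list. Heat shock genes were 2 without untreated wt replicate 1, 1 without untreated wt replicate 2, either untreated KO array, either wt 2 h array, KO 2 h replicate 1 or wt 6 h replicate 1, and 11 without KO 2 h replicate 2.

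Limma called 304 genes, 56 higher and 248 lower, of which 2 and 17 differed at least 2-fold. After quantile normalization 71 were higher and 120 lower, which moved the share higher from 18.4% to 37.2%, and with a mean log2 of at least 7 the count was 201. The count was 141 and 89 without untreated wt replicates 1 and 2, 78 and 121 without untreated KO replicates 1 and 2, 65 and 77 without wt 2 h replicates 1 and 2, 168 and 667 without KO 2 h replicates 1 and 2, 123 without wt 6 h replicate 1 and 164 without KO 6 h replicate 2. Of the 46 named and called genes 13 kept their call whichever array was left out, among them Cetn4 (on the probe set used), Nnmt, Il18, Hspb1, Irgm1, Igfbp1, Pck1, Herpud1 and Alas2.

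The KO response minus the wt response tests whether a gene changed differently after APAP in the genotypes. At 2 h limma called 5 genes. Arrdc3, an arrestin-domain gene, differed by 3.41 ± 0.33, with log2 means of 11.22 untreated and 8.71 at 2 h in wt against 9.64 and 10.55 in KO. Id2, an inhibitor of helix-loop-helix transcription factors, differed by 1.77 ± 0.23. Cetn4 (-3.27 ± 0.24, but -0.50 with adjusted p = 0.269 on its other probe set and -1.88 with the mean of probe sets), Sftpa1 (-2.52 ± 0.28) and Col12a1 (-2.07 ± 0.19) responded less in KO. Col12a1 kept its call whichever array was left out, as did Cetn4 on the probe set used. Arrdc3 lost its call without wt 2 h replicate 2 (adjusted p = 0.0622). Id2 lost its call with a mean log2 of at least 7 (adjusted p = 0.0768), with the replicate block (0.0659), and without any untreated array, any wt array at 2 h or 6 h, or KO 2 h replicate 1, with the highest adjusted p of 0.196 without untreated wt replicate 1. Sftpa1 lost its call without untreated wt replicate 1 (0.126), untreated KO replicate 2 (0.0988), either wt 2 h array (0.117) or KO 2 h replicate 1 (0.0779).

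As groups at 2 h, immediate early genes rose more in KO, with a median difference of 0.89 (adjusted p = 1.22e-09), as did heat shock proteins with 0.626 (adjusted p = 8.95e-11), or 0.33 without KO 2 h replicate 1. Cholesterol synthesis genes, which fell in wt and less in KO, had a median difference of 0.526 (adjusted p = 1.58e-08), and 0.318 without untreated KO replicate 1. Each had adjusted p = 0.543 with an estimated correlation. In each of these 3 lists 3 members were called adjusted over the list alone, among them Egr2 (2.48 ± 0.36), Hspb1 (2.58 ± 0.52, and 0.18 on its dim probe set) and Stard4 (1.01 ± 0.23), and over all genes limma called 0 of them. NRF2 targets differed by a median of 0.073 (adjusted p = 0.00051, and adjusted p = 0.543 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.0662). The p53 targets did not pass, at -0.127 (adjusted p = 0.676, and adjusted p = 0.824 with an estimated correlation). Cell cycle genes differed by a median of -0.304 (adjusted p = 0.0319, and adjusted p = 0.543 with an estimated correlation), and this call ended without untreated wt replicate 1, untreated KO replicate 1 or wt 2 h replicate 1 (adjusted p = 0.0833, 0.0801 and 0.259). In all, 2606 genes had an unadjusted p under 0.05. The count of 5 was 10 after quantile normalization, 11 with a variance trend, 23 in a fit of the compared groups only, 1 with a mean log2 of at least 7 and 8 with log2 of the value plus 16. It was 3 without untreated wt replicate 1, untreated KO replicate 2 or KO 2 h replicate 1, 2 without wt 2 h replicate 2, 11 without untreated KO replicate 1, 33 without KO 2 h replicate 2 and 18 without either KO 6 h array.

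At 6 h the KO response of immediate early genes was smaller than the wt response, with a median difference of -1.69 (-0.984 without KO 6 h replicate 2). Of 31 members 5 were called (24 adjusted over the list alone), among them Fos (-3.95 ± 0.45), Myc (-3.97 ± 0.62) and Ier2 (-2.42 ± 0.32). Neutrophil markers differed by a median of -1.55, with 4 of 14 called (8 adjusted over the list alone), among them S100a8 (-2.50 ± 0.34) and Cxcr2 (-3.22 ± 0.48). Inflammatory genes differed by a median of -0.63 (-0.272 without KO 6 h replicate 2), with 1 of 28 called (10 adjusted over the list alone). Their count was 0 without any untreated or wt 2 h array, 2 without wt 6 h replicate 2 and 9 without KO 6 h replicate 1. The p53 targets differed by -0.24, with 0 of 35 called (7 lower and 1 higher adjusted over the list alone) and Btg2 at -2.52 ± 0.56 (adjusted p = 0.0837). Periportal genes included Pck1, at -1.48 ± 0.15. Gprc5a (-4.00 ± 0.48) rose less in KO. Gadd45g (-4.74 ± 0.48) rose from a log2 mean of 5.91 to 9.95 in wt and went from 9.11 to 8.41 in KO (adjusted p = 0.139). Igfbp1 (-3.13 ± 0.34) moved in opposite directions, from 9.17 to 11.37 in wt and from 9.01 to 8.07 in KO. Cetn4 (-3.33 ± 0.24) responded less in KO on the probe set used, while its other probe set differed by -0.38 (adjusted p = 0.351) and the mean of its probe sets by -1.85. Abcc4 (1.84 ± 0.24) rose more in KO. Atoh8, a helix-loop-helix transcription factor (1.66 ± 0.17), moved in opposite directions, from 8.31 to 7.08 in wt and from 8.02 to 8.46 in KO.

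Limma called 83 genes in this interaction at 6 h, 15 higher and 68 lower, and 2764 had an unadjusted p under 0.05. The count was 21 and 31 without untreated wt replicates 1 and 2, 40 and 18 without untreated KO replicates 1 and 2, 43 and 223 without wt 6 h replicates 1 and 2, and 286 and 46 without KO 6 h replicates 1 and 2. Of the 32 named and called genes Fos, Gadd45g, Gprc5a, Igfbp1, Cetn4 (on the probe set used), Pck1 and Atoh8, among others, kept their call whichever array was left out. Abcc4 lost its call without untreated KO replicate 2 (adjusted p = 0.0537), Ier2 without untreated wt replicate 2 or untreated KO replicate 2 (0.055 and 0.0537), and S100a8 without either untreated wt array or untreated KO replicate 2 (0.0639, 0.0578 and 0.0618). Myc lost its call without either untreated wt array, untreated KO replicate 2, either wt 2 h array, wt 6 h replicate 1 or KO 6 h replicate 2, up to 0.11. Cxcr2 lost its call without any untreated array or KO 6 h replicate 2, up to 0.088. Immediate early genes called were 2 and 1 without untreated wt replicates 1 and 2, 3 and 1 without untreated KO replicates 1 and 2, 2 without either wt 2 h array, wt 6 h replicate 1 or KO 6 h replicate 2, and 16 without KO 6 h replicate 1. Neutrophil markers called were 0 without either untreated wt array or untreated KO replicate 2, 2 without untreated KO replicate 1 or wt 6 h replicate 1, and 1 without KO 6 h replicate 2. The list tests gave adjusted p of 1.1e-17 for immediate early genes, 5.93e-07 for neutrophil markers, 1.23e-06 for inflammatory genes and 0.00432 for p53 targets, each with adjusted p = 0.309 with an estimated correlation. The NRF2 list had a median of 0.193 (adjusted p = 0.0148, and adjusted p = 0.383 with an estimated correlation). Its call ended after quantile normalization (adjusted p = 0.112) and without untreated wt replicate 2, untreated KO replicate 2 or KO 6 h replicate 1 (adjusted p = 0.0511, 0.0976 and 0.114).

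Over both genotypes, ribosome biogenesis genes stood higher at 6 h than at 2 h in 22 of 23 members, among them Mybbp1a (1.41 ± 0.12). NRF2 targets stood higher in 19 of 36 and lower in 4 (22 and 4 adjusted over the list alone), with Pgd, of the pentose phosphate pathway, at 1.78 ± 0.10 and Akr1b8 at 1.82 ± 0.10. Fatty acid oxidation genes stood lower at 6 h in 21 of 25 (24 adjusted over the list alone), among them the nuclear receptor gene Ppara (-1.32 ± 0.13) and Cpt1a (-0.95 ± 0.10). Immediate early genes stood lower in 16 of 31 and higher in 3 (18 and 4 adjusted over the list alone), with Fos at -3.05 ± 0.23. By array mean this list rose in wt and fell in KO.

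Limma called 7044 genes between 6 h and 2 h, 3373 higher and 3671 lower, with 4 arrays on each side. The list tests gave adjusted p of 3.11e-12 for ribosome biogenesis, 2.26e-05 for NRF2 targets, 3.3e-08 for fatty acid oxidation and 0.00144 for immediate early genes. These were adjusted p = 0.455, 0.247, 0.455 and 0.537 with an estimated correlation. Of the 122 named and called genes, 120 kept their call whichever array was left out, and the exceptions were Cd24a and Cd3e.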

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

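Of the tests in this part, those of the flanking chromosome within 20 Mb of Pml and of other splits of the arrays were written before the result was seen; those of genes off chromosome 9, of the labels, of the blood share, of a mislabelled 6 h array and of the chemokines were chosen only after it was seen.

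At 2 h after APAP, the responses of KO and wt liver differed in 5 genes by the test of the difference itself. Arrdc3 (3.41) and Id2 (1.77, a call that ended with a mean log2 of at least 7 and with the replicate block) had a higher KO than wt response on the log2 scale. Cetn4 (-3.27, but -0.50 with adjusted p = 0.269 on its other probe set), Sftpa1 (-2.52) and Col12a1 (-2.07) had a lower one. As groups, immediate early genes (median 0.89), heat shock proteins (0.63), cholesterol synthesis genes (0.53) and NRF2 targets (0.07) differed upward and cell cycle genes (-0.30) downward, each with adjusted p = 0.543 with an estimated correlation. The number of genes changed with the array left out, as given above.

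At 6 h the responses differed in 83 genes. Among those with the largest values, the KO response was higher for Id1 (2.82), an inhibitor of helix-loop-helix factors, Arrdc3 (2.26), the transporter genes Slc1a4 (1.95), Abcc4 (1.84) and Slc17a4 (1.73), Atoh8 (1.66), Cldn2 (1.56), a tight junction gene, Pfn2 (1.5), Dexi (1.49) and Derl3 (1.47). It was lower for Gadd45g (-4.74), Gprc5a (-4.00), the growth regulators Myc (-3.97) and Fos (-3.95), Cetn4 (-3.33, but -0.38 with adjusted p = 0.351 on its other probe set), Cxcr2 (-3.22), Igfbp1 (-3.13), Nrg4 (-2.85), a neuregulin, Alas2 (-2.68) and S100a9 (-2.54). Of these 20 genes Atoh8, Dexi, Gadd45g, Gprc5a, Fos, Cetn4 (on the probe set used) and Igfbp1 kept their call whichever array was left out. The other 13 lost it without at least 1 array. Of the 32 genes the naming rule gives here, 22 and 20 lost their call without untreated wt replicates 1 and 2, 18 and 23 without untreated KO replicates 1 and 2, 11 without either wt 2 h array, 2 without either KO 2 h array, 15 and 1 without wt 6 h replicates 1 and 2, and 1 and 17 without KO 6 h replicates 1 and 2. The number of genes changed with the array left out, as given above. With the replicate block the calls of Id1, Slc1a4, Pfn2 and Derl3 ended (adjusted p = 0.0558, 0.0526, 0.0544 and 0.0608).

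As groups at 6 h, the KO response stood above the wt response in NRF2 targets (median 0.19) and endoplasmic reticulum chaperones (0.44), with adjusted p = 0.0148 and 0.00432, and adjusted p = 0.383 and 0.607 with an estimated correlation. It stood below it in immediate early genes (-1.69), neutrophil markers (-1.55), inflammatory genes (-0.63), bile duct markers (-0.45), p53 targets (-0.24) and erythroid markers (-0.10), each with adjusted p = 0.309 with an estimated correlation. Genes of the integrated stress response (-0.19) and periportal genes (-0.07) had adjusted p = 0.607 and 0.414 with an estimated correlation, and their direction was not stable: both medians turned to 0.025, without KO 6 h replicate 2 and replicate 1 respectively. The erythroid call ended without untreated wt replicate 1, untreated KO replicate 1 or KO 6 h replicate 1 (adjusted p = 0.102, 0.0534 and 0.0691). The periportal call ended without untreated KO replicate 1 or KO 6 h replicate 1 (0.0678 and 0.164), the chaperone call without untreated wt replicate 1 (0.1) and the bile duct call without KO 6 h replicate 2 (0.0511). The NRF2 call ended without some arrays, as given above. The call of the integrated stress response ended without untreated wt replicate 2, untreated KO replicate 1, any 2 h array, wt 6 h replicate 2 or KO 6 h replicate 2 (0.0501 to 0.896).

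Probe sets that match several genes stand outside the comparisons above. In wt liver at 6 h, 312 of the 1709 tested stood higher and 296 lower than in untreated wt liver, and they carry no single gene name.

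Genes that differ between KO and wt liver over the 3 conditions were more frequent near Pml. Of 397 tested genes within 20 Mb of Pml, 16 (4.03%) were called, among them Nnmt, Il18, Cd3e and Pkm, against 287 of 16640 elsewhere (1.72%), an odds ratio of 2.39 with a one-sided Fisher p of 0.00208. This is consistent with flanking sequence from the strain in which Pml was disrupted, and an effect of Pml on its neighbours was not tested. Of the called genes, 92.7% (281 of 303) lie off chromosome 9, which flanking sequence cannot carry, so this share tests nothing. Sequence from that strain elsewhere, and effects of flanking genes such as Nnmt or Il18 on other genes, were not tested and stay open. Chance is not excluded for the 304 genes called, since 2 of 100 splits of the arrays, the real one included, gave as many, and the highest other split called 464.

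The array labelled untreated KO replicate 2 has a Pml value within the range of the wt arrays. An exchange with an untreated wt array is argued against by Pml, since the lower untreated wt array lies 0.68 above the highest of the other 5 KO arrays. The real split called 304 genes, and the 5 splits that exchange untreated arrays only called 185, 213, 229, 273 and 464, the last with this array and untreated wt replicate 1 exchanged; the cause was not tested. A wrong label on this array alone stays open, since of the 4 genes other than Pml that part all other KO and wt arrays by more than 0.2, 1 (Nnmt, at 10.36 against 7.36 to 8.98 in wt, which lies near Pml) was on the KO side and Igfbp3, Krtap1-4 and Gm10825 were not. No biological explanation was tested.

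Neutrophil markers stood lower in KO than in wt liver at 6 h, with a median of -1.61 over 14 genes. The responses differed by a median of -1.55 (adjusted p = 5.93e-07, and adjusted p = 0.309 with an estimated correlation). Of these genes 4 were called, and fewer without some arrays, as given above. Lymphocyte and NK cell markers argue against less blood of every kind in KO tissue as the whole cause (median -0.21 over 16 genes). The 95% bootstrap interval over genes, not livers, was -0.32 to -0.04. Erythroid markers (median -0.15, mean -0.796, 5 genes) do not argue against less blood. A wrong genotype label on a KO 6 h array is argued against by Pml, since the lowest wt array lies 0.65 above the higher one. Pml cannot show a wrong time or treatment label, which stays open for KO 6 h replicate 2 (first component 19.8). A lower level of neutrophil attracting chemokines in KO liver stays open: Cxcl1 differed by -2.41 (adjusted p = 0.0041) and Cxcl2 by -5.21 ± 1.63 (adjusted p = 0.0708). Fewer neutrophils in the tissue and lower expression per cell cannot be told apart with these arrays, and the chemokine test is a hypothesis from the same data.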

How the results depend on the processing

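Of the alternatives in this part, log2 of the value plus 16 and the counts of list members without an array were chosen after the data were examined. The cause of a change was not tested.

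Of 1390 values of named genes, of which 771 were called, 1349 kept their direction and side of the test after quantile normalization, 8 passed newly and 33 no longer passed. The corresponding numbers were 1369, 0 and 21 with no filter, 1385, 3 and 2 with the mean of probe sets, 1368, 20 and 2 with a variance trend, 1365, 19 and 6 with log2 of the value plus 16, and 1266, 27 and 97 in a fit of the compared groups only. With a mean log2 of at least 7, which drops dim genes, they were 1016, 11 and 1. With 1 array left out they were 15514, 198 and 968 over all arrays, and in these settings the direction of a called named gene did not reverse. Of 319 list results, 122 passed at the preset correlation and 0 with an estimated one. After quantile normalization 298 list results kept their side, 10 passed newly and 11 no longer passed.

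Counts of genes that moved by over 1.5 times were these. KO against wt in untreated liver had 1 gene, and limma called 0 with no filter, 0 after quantile normalization, 0 with log2 of the value plus 16 and 2 in a fit of the compared groups only; 660 had an unadjusted p under 0.05. KO against wt at 2 h had 342 and 52 in a fit of the compared groups only, and at 6 h 1538 and 142, where the error rests on fewer arrays. The mean of 3 conditions had 304, 201 with a mean log2 of at least 7 and 191 after quantile normalization. The difference between the responses at 2 h had 5, 1 with a mean log2 of at least 7, 10 after quantile normalization, 11 with a variance trend, 23 in a fit of the compared groups only and 8 with log2 of the value plus 16.

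Replicate numbers were tested as a block. The differences between replicates 1 and 2 correlated between groups at -0.134 to 0.185 over 15 pairs of groups, 4 of them above 0.1, so the numbers are not used to pair arrays. With the block, KO against wt called 0 genes in untreated liver and 550 at 2 h; among named genes 1350 values kept their side, 9 passed newly and 31 no longer passed, and among lists 314, 1 and 4.

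With 1 array left out a group holds a lone array, which is assumed to vary like the other groups, and the number of arrays limits what can be called. Lowest and highest counts were 800 and 2317 for wt at 2 h, 4162 and 6727 for wt at 6 h, 2935 and 5471 for KO at 2 h and 3845 and 6072 for KO at 6 h, each against untreated. For KO against wt they were 0 and 3 untreated, 8 and 777 at 2 h, 172 and 1691 at 6 h and 65 and 667 over the 3 conditions. For the difference between the responses they were 2 and 33 at 2 h and 18 and 286 at 6 h, and for 6 h against 2 h 5273 and 6713. The lows lay without wt 2 h replicate 1 (wt at 2 h, KO against wt at 2 h and over the 3 conditions), untreated wt replicate 2 (wt at 6 h), untreated KO replicate 2 (KO at 2 h, responses at 6 h), KO 6 h replicate 1 (KO at 6 h), wt 6 h replicate 1 (KO against wt at 6 h) and wt 2 h replicate 2 (responses at 2 h).

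Of the list results, 3638 kept their side with 1 array left out, 108 passed newly, 78 no longer passed and 4 reversed, each with an adjusted p that no longer passed. Endoplasmic reticulum chaperones in untreated KO against wt ran from 0.006 without untreated wt replicate 2 (adjusted p = 0.944) to 0.251 without untreated wt replicate 1. Cholesterol synthesis in the same comparison ran from -0.028 without untreated KO replicate 2 (0.692) to 0.376 without untreated KO replicate 1. The integrated stress response ran from -0.539 to -0.031 (0.931) in KO against wt at 6 h and from -0.653 to 0.025 (0.896) in the difference between the responses at 6 h, without KO 6 h replicates 1 and 2 respectively. The test weighs all members, so it can change direction while the median keeps its sign.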

Other observations

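In this part the test of transcripts running past gene ends and that of other splits of the treated arrays were written before the result was seen, and that of quantile normalization on dim genes was chosen only after it was seen.

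Markers of cells that hold a small share of the liver moved in both directions in wt liver at 6 h against untreated wt liver. Among stellate cell and fibroblast markers the collagen gene Col3a1 (-0.91 ± 0.17) stood lower, with a list median of -0.3 (adjusted p = 0.352, and adjusted p = 0.755 with an estimated correlation). Among erythroid markers Alas2 stood higher (1.47 ± 0.30), with a list median of 0.112 (adjusted p = 0.264, and adjusted p = 0.555 with an estimated correlation). Among fat tissue markers Cidec (5.42 ± 0.28) and Fabp4, a fatty acid binding protein (2.04 ± 0.31), stood higher, with a list median of 0.092 (adjusted p = 0.19, and adjusted p = 0.469 with an estimated correlation); liver expresses Cidec as well. Among pancreas markers 2 of 9 stood lower, among them Prss2, a trypsinogen (-0.47 ± 0.11, a call that ended without untreated wt replicate 2 with adjusted p = 0.0509), with a list median of -0.04 (adjusted p = 0.49, and adjusted p = 0.721 with an estimated correlation). Lymphocyte and NK cell markers had a median of -0.13 (adjusted p = 0.507, and adjusted p = 0.788 with an estimated correlation) and sinusoidal endothelial markers one of -0.379 (adjusted p = 0.19, and adjusted p = 0.688 with an estimated correlation). These genes were chosen after their values were seen.

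Genes called between 6 h and 2 h were counted in other splits of the 8 treated arrays into 4 and 4. The real split called 5736 with genotype as a term, the highest other 12. The others mix 2 h and 6 h arrays, so low counts were built in and 1 of 35 giving as many cannot exclude chance.

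Genes that are dim in untreated liver stand lower in KO than in wt liver at 2 h, but the shift is not particular to them. The median was -0.067 over 8435 tested genes with an untreated mean log2 under 7 and -0.13 over the other 8617, and dim genes were 41.5% of the genes called lower and 49.5% of those tested. For the dim genes alone 2 explanations were tested without deciding between them, and neither covers the shift in the others. The first was that transcripts run past the ends of highly expressed neighbours. Of 8427 dim genes with a position, the 219 within 10 kb of a gene at 11 or more had a median difference of -0.123, against -0.065 for the others. The difference of -0.059 (one-sided permutation p = 9e-04 from 10000 permutations) lies between the bound of -0.1 that the explanation needed and that of -0.05 that would have excluded it. The other was that arrays differ in the level of dim probe sets. Of 113 dim genes called lower, 60 (53.1%) stayed called lower after quantile normalization, and their median went from -0.70 to -0.65, so the level of the arrays may account for a part of these calls.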
